A study of Cereibacter sphaeroides with 2 samples.

How the data were processed

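Total RNA of the plasmid strain and the vector strain was labelled directly, per the labels, with 2 µg of pooled RNA per dye for 15 min at 85 °C, and hybridised on 2-colour Agilent arrays. The arrays were scanned and extracted with Feature Extraction 10.7.1.1, per the file headers. The intensity values used are the raw median brightness of each spot and of its local background, per the file headers. The scanner software's log ratio is log10 of Cy5 over Cy3 of its own processed signals, per the file headers and the values. The authors' deposited value table holds log2 ratios per spot, and the submitters' processing notes name limma. Its method is not stated. Set against the scanner values in file order, it lay within 0.0218 (replicate 1) and 0.0154 (replicate 2) of log2 Cy3 over Cy5 without background correction and with loess. Its scale, direction and order were therefore read from the values. Its medians were -0.00723 and -0.00914.

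In R 4.3.3 with limma 3.58.1, background was corrected with normexp (offset 50) on the median signals. The plan had named mean signals, and the median was used since the files hold that column. Each array was normalized by loess with control spots at weight 0, and 536 control spots and 1 spot per array marked as an outlier were left out. Spots were averaged per probe and probes per feature, and features with no probe well above background in at least 1 channel on both arrays (9 of 4516) were left out. Log2 ratios were tested against 0 with lmFit and eBayes, with Benjamini-Hochberg adjustment. With 2 arrays there is 1 residual degree of freedom per feature, to which the prior added 2.01. Cultures were pooled before labelling, so p-values measure the spread between 2 pools. Both arrays lay on 1 slide, so slide and scan could not be tested as batches.

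On simulated ratios with the same spread and 200 changed features among 4507, the test recovered 99% of 2-fold and 87% of 1.5-fold changes and called 18 unchanged features. When each feature was given a bias of SD 0.187 common to both arrays, taken from the disagreement of probes, 1159 unchanged features (26.9%) were called and 18 were 1.5-fold on both arrays. That SD was for a mean of 3 probes. It may understate the bias of the 130 features with 1 probe and the 70 with 2. Without a dye swap such a bias is not removed.

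Before the data were examined, these features were chosen to be named: any for the CcsR locus, RSP_6037 or flhR; the 12 largest rises and 12 largest falls among called features with 1 direction on both arrays; and up to 4 members of each of 28 gene lists. None of the 28 lists matched a feature (0 lists), since 4372 identifiers are numbers that matched 0 gene identifiers of the reference table (assembly ASM332471v1), and gene list tests were not run. Of unnamed numeric identifiers only the leading ones are printed. The other labelled features (all those called and at least 1.5-fold on both arrays) were chosen after their values were seen, as were the groups by kind of label and the runs of identifiers, where a gap of over 20 starts a new run. These 11 groups were tested with camera at a preset correlation of 0.01, which treats features as nearly independent. An estimated correlation rests on 1 residual degree of freedom. No group passed with it, so a failure there says little. A further 2 intergenic features whose numbers match small RNAs from the literature were looked at, did not pass the test and are not listed. A garbled apostrophe in some names is written as an apostrophe. Of the 144 labelled features 74 had 1 spot per array. A channel not well above background on either array allows only a bound, computed per channel after loess and Aquantile and open to dye bias.

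Alternatives covered background correction, offset 16, the scanner software's processed signals, median centring, scale normalization, the dim filter, outlier-marked spots, the median over probes, the authors' value table, eBayes settings, a test per probe, an unpaired fit of the channels (which needed Aquantile normalization as well), a 2-fold threshold and each array alone. A correction for base content was not run, as probe sequences were not used here.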

Results

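Transcript levels were measured in Rhodobacter (Cereibacter) sphaeroides 2.4.1, a purple alphaproteobacterium, carrying either a plasmid for the small RNAs CcsR1-4 or the empty vector pRK415. The CcsR RNAs are homologous small RNAs of this species that lie next to each other in the genome and are also known as RSs0680a to RSs0680d. Cells were grown aerobically to an OD660 of 0.4. Per the labels, 6 cultures were grown independently, cultures 1 to 3 were pooled for replicate 1, and cultures 4 to 6 for replicate 2. The plasmid strain carried Cy3 and the vector strain Cy5 on both 2-colour arrays, so strain and dye cannot be told apart in any ratio given here. All ratios are plasmid strain over vector strain, and SD values are over the 2 arrays (n = 2 pools of 3 cultures).

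Each array held 15208 spots that were not controls. The median intensity was 4528.5 in Cy3 and 5203.5 in Cy5 for replicate 1, and 4551.75 in Cy3 and 4951 in Cy5 for replicate 2. The negative control spots had medians of 1740 and 1811 on the first array and 1777 and 1707 on the other. Spots well above background made up 94.7% (Cy3) and 83.5% (Cy5) in replicate 1, against 95.1% and 76.9% in replicate 2. The 2 arrays limit the precision of every value.

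The comparison asked which transcripts differ when CcsR1-4 are supplied from a plasmid. The 3 features for the antisense strand of intergenic region 0680, at positions 691544 to 692463 in the feature labels (replicon and build not given in the sources used here), rose most of all tested features. With the scanner software's processed signals 0680b ranked 4 and the other two stayed among the leading 2. Feature 0680c had a log2 ratio of 1.77 ± 0.07 (SD, n = 2), 0680b 1.76 ± 0.09 and 0680a 1.73 ± 0.04. These correspond to 3.41-fold, 3.39-fold and 3.31-fold. Each had an adjusted p of 0.0147 in limma and was higher on 2 of 2 arrays. The number 0680 is shared with the literature name of the CcsR genes, but the files do not pair the features with CcsR. Each of these features had 1 spot per array. No feature was labelled RSP_6037 or flhR, and none was named CcsR.

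Other labelled transcripts rose with the plasmid. Each feature in this paragraph had 1 spot per array, so its SD over the arrays cannot show a bias of its single probe. The sense strand of intergenic region 1543 (1632533 to 1632899), whose number is shared with the small RNA RSs1543, called SorY in the literature, had a log2 ratio of 1.28 ± 0.04 (2.42-fold; limma adjusted p = 0.0147). It was 0.60 with median centring in place of loess. The antisense strand of region 0234 rose by 0.87 ± 0.03 and the feature at the 3' end of RSP3773 by 0.87 ± 0.00330. The antisense feature of RSP3616 had 0.87 ± 0.02, antisense feature No1 of RSP3018 0.79 ± 0.05, and the sense strand of region 0827 (858004 to 858191) 0.72 ± 0.11. Antisense feature No2 of RSP3018 had 0.18 ± 0.16 and was not called (limma adjusted p = 0.127). The RSP3616 value was 0.41 with the scanner software's processed signals and 0.50 with median centring, and that of region 0827 was 0.45 with the processed signals.

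The antisense strand of region 0293 had a log2 ratio of 0.64 ± 0.04, the antisense feature of RSP3316 0.63 ± 0.04, and the 3' feature of RSP3584 0.60 ± 0.02. The features of region 0293, RSP3584 and RSP3594 had 1 spot per array. With median centring region 0293 had 0.08 and lost its call, and RSP3584 turned to -0.037. With the scanner software's processed signals RSP3316 had 0.19 and lost its call, and region 0293 and RSP3584 had 0.32 each. For the 3' feature of RSP3646 (1.07 ± 0.06) its 2 probes disagreed, at 0.17 and 1.97. The antisense feature of RSP3594 was not well above background in Cy5 on either array, so only a bound is given for it. That lower bound was 0.689-fold, which does not exclude a fall, so its direction is uncertain too. Its log2 ratio was 0.30 without background correction. Its call ended in the unpaired fit of the channels (limma adjusted p = 0.0938).

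Among the labelled transcripts that fell, the sense strand of intergenic region 0552 changed most, with a log2 ratio of -1.70 ± 0.08 (SD, n = 2; limma adjusted p = 0.0147; lower on 2 of 2 arrays). The antisense strand of region 0360 had -1.04 ± 0.08, that of region 2378 (2509141 to 2509377) -0.88 ± 0.06, and the sense strand of region 0272 -0.84 ± 0.03. The sense strand of region 0682 (694011 to 694910), near region 0680 by its coordinates, had -0.82 ± 0.06, with 3 probes between -0.95 and -0.58. It was -1.52 with median centring and -0.42 with the scanner software's processed signals. The remaining 10 labelled falls lay between -0.85 and -0.64. They were the sense strands of regions 1943, 0775, 1603, 2363 and 0635, the antisense strands of regions 0252, 0510, 0211 and 1156, and the antisense feature of RSP_1198. Region 1603 (-0.79 ± 0.19) lost its call with the processed signals (-0.82, limma adjusted p = 0.0521) and in the unpaired fit of the channels (-0.79, limma adjusted p = 0.0613), with a log2 ratio about as large. Without background correction the values of regions 1943, 1603 and 1156 were -0.46, -0.29 and -0.31. With median centring those of regions 0635, 2363, 0510, 0252 and 0775 and of RSP_1198 were between -1.59 and -1.24, and with the processed signals region 1943 had -1.63, region 0510 -0.40 and region 0211 -0.27. The 2 probes of region 0635 were at -1.39 and -0.07. The features of regions 2378, 1943 and 0252 had 1 spot per array. Region 0552 had -2.39 with median centring and -1.44 with the processed signals. The features of regions 0552, 0682, 2363, 0510, 0252 and 0635 were bright, with mean log2 intensities between 17.3 and 17.8. The rise of region 1543 was on a feature about as bright (17.3). The share of brightness in these falls was not tested.

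**Figure D1:**
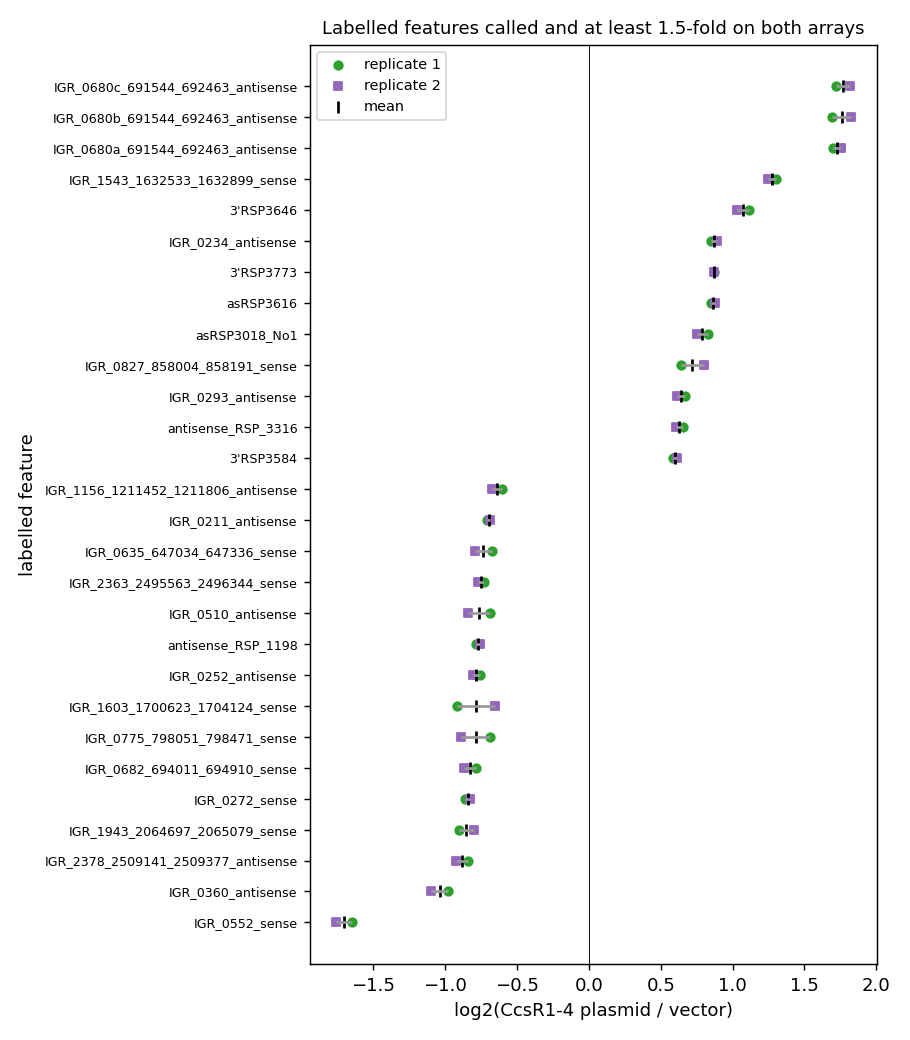
Log2 ratio (plasmid strain over vector strain, x axis) of the 28 labelled features called by limma, at least 1.5-fold on both arrays and with each channel well above background on at least 1 array (y axis). Circles are replicate 1, squares replicate 2 and ticks the mean of both; the 3 features of region 0680 sit between 1.69 and 1.83.

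By kind of label, 28 of the 58 intergenic features in sense direction fell and 10 rose, with a mean log2 ratio of -0.16 (camera adjusted p = 0.0448 over 11 groups; adjusted p = 0.456 with an estimated correlation). This call also ended with the scanner software's processed signals (mean -0.10, adjusted p = 0.266), with both channels above background (mean -0.16, adjusted p = 0.0790) and with the median over probes (mean -0.16, adjusted p = 0.0801), and the mean was -0.39 with median centring (adjusted p = 6.76e-06). The intergenic sense features were brighter (median log2 intensity 15.0) than the numeric identifiers (11.8), and the share of brightness in their fall was not tested. Among the 48 intergenic antisense features 10 rose and 21 fell. Their median log2 ratio was -0.152, close to the median of -0.156 for the intergenic sense features. Their mean, which includes the largest rises of all tested features, was -0.04 (camera adjusted p = 0.115). It passed with median centring (-0.25, adjusted p = 0.00014), without background correction (-0.02, adjusted p = 0.0243) and with the authors' deposited values (-0.02, adjusted p = 0.0220), and was 0.06 with the processed signals (adjusted p = 0.906). Of 23 features antisense to a gene, 9 rose and 4 fell (mean 0.20; adjusted p = 0.192). Of the 14 features at gene ends or with other labels, 6 rose and 3 fell (mean 0.22; adjusted p = 0.192). With median centring these means were 0.10 and 0.14, and neither passed under any alternative.

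Numeric identifiers made up 4364 of the 4507 tested features and are not paired with gene names in the files. Of these, 1064 were called higher and 1052 lower. The largest rises were those of 640073247 (1.15 ± 0.14) and 640073136 (1.02 ± 0.18). The probes of 640073136 ran from -0.01 to 2.69, and its value was 0.41 and not called with the median over probes. The largest falls were those of 640710007 (-2.40 ± 0.18) and 640709959 (-2.39 ± 0.24), each with a limma adjusted p of 0.0147. Both belonged to a run of 54 features with close identifiers that included the brightest on the arrays, with a median log2 intensity of 17.9. In this run 52 features were called lower, 0 higher, and 35 were at least 1.5-fold lower on both arrays. Of the 54 features 46 had 1 spot per array, so a spread over the arrays cannot show a bias of their single probes. Its mean log2 ratio was -0.81 ± 0.11, and -1.61 with median centring. The camera adjusted p was 1.35e-16 at the preset correlation and 0.456 with an estimated one. The preset value treats features as nearly independent, and no group passed with the estimated one, so neither p-value settles the fall of the run.

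**Figure D2:**
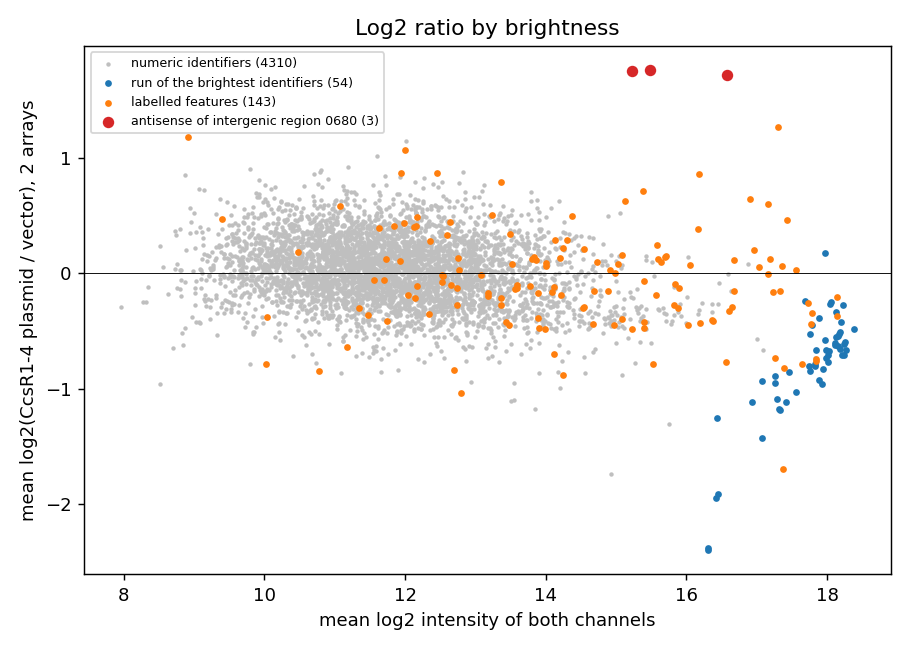
Mean log2 ratio over the 2 arrays (y axis) against the mean log2 intensity of both channels (x axis), 1 point per tested feature, including 84 with 1 channel not well above background on either array. The 54 features of the bright run lie at the right with a mean of -0.81, and the 3 features of region 0680 lie above all others.

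Over all 4507 features, limma called 1099 higher and 1108 lower at an adjusted p under 0.05, 49.0% of those tested. The fit of the channels as unpaired samples, with Aquantile normalization, called 333 higher and 491 lower, and the authors' deposited values gave 1664 higher and 1253 lower. Most changes were small, with a median absolute log2 ratio of 0.33 among the called features. At least 1.5-fold in the same direction on both arrays were 74 features higher and 116 lower, against 3 in opposite directions. In 3 of the higher and 1 of the lower features a channel was not well above background on either array, so their size is uncertain. RSP3594 was among the higher ones, and its direction is uncertain too. With both channels required above background on both arrays, 68 higher and 115 lower remained. All 190 features at least 1.5-fold in the same direction were also called by limma. The 12 largest rises among called features held 6 labelled and 6 numeric features. Of the labelled, 5 were well above background in both channels and RSP3594 was not, so that its place is uncertain. The 12 largest falls held 1 labelled and 11 numeric features. Of these numeric falls 8 belonged to the bright run, against 0 of the numeric rises. That run also held 35 of the 116 features at least 1.5-fold lower.

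The log2 ratios of the 2 arrays correlated across features (Pearson r = 0.860, Spearman rho = 0.8496), and 86.3% of features had the same direction on both. Features are not independent replicates, and a dye bias shared by both arrays would raise this correlation. Without background correction 1709 features were called higher and 1275 lower, and 20 were 1.5-fold higher and 71 lower on both arrays. With the scanner software's processed signals 194 were 1.5-fold higher and 181 lower, so the side with more features turned. With the probe instead of the array as the replicate, limma called 0 of the 4307 features with 3 probes, while 914 had an unadjusted p under 0.05. The smallest limma adjusted p was 0.0557. Of the 2065 array calls among these features, 1473 (71.3%) had all 3 probes in 1 direction.

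**Figure D3:**
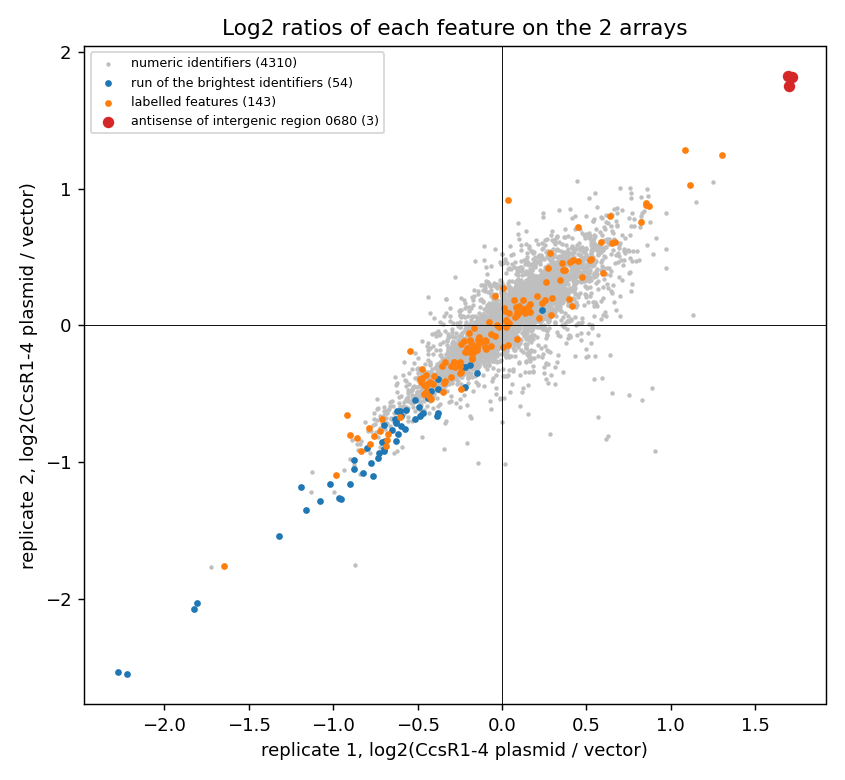
Log2 ratio of each tested feature in replicate 1 (x axis) and replicate 2 (y axis), including 84 with 1 channel not well above background on either array. Points along the diagonal changed alike on both arrays (Pearson r = 0.860 across features).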

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

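The tests in this part were chosen after the results were seen. Several kinds of control spots outside the comparison gave signal above the 77 negative control spots, of which 1.30% (Cy3) and 0.649% (Cy5) were well above background over both arrays. In Cy3 the share was 92% for the 200 E1A spots, 75% for EQC, 68.6% for ETG, 55.6% for DCP and 100% for GE spots. In Cy5 it was 19.3% for E1A, 16.7% for EQC, 33.3% for ETG, 27.8% for DCP and 100% for GE spots. The RC spots were at 0.694% in Cy5, just above the negative controls, and at 0.694% in Cy3, below them. The DarkCorner spots were at 0% in both channels. No explanation was tested for these values.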

How the results depend on the processing

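The probe as the replicate, the turned sign of array 2, the fit without the bright run and the groups by label were added after the results were seen. Without background correction 1709 features were called higher, and 1664 were with the authors' deposited values, and at 1.5-fold on both arrays 20 were higher under each and 71 and 73 lower. With the scanner software's processed signals 194 were 1.5-fold higher and 181 lower. In the processing of the report, 7 were 2-fold higher and 13 lower on both arrays. Replicate 2 alone gave 149 higher and 163 lower at 1.5-fold. Replicate 1 alone gave 153 higher and 127 lower, so there the side with more features turned. The test per probe called 2663 probes higher and 2807 lower, the fit with no replicate block 333 features higher and 491 lower. The probe as the replicate called 0 higher and 0 lower (914 at an unadjusted p under 0.05, smallest limma adjusted p 0.0557). So did array 2 with its sign turned (6 unadjusted), where the shared change becomes the residual. Pearson and Spearman correlations of the arrays were 0.944 and 0.919 without background correction, 0.945 and 0.919 for the authors' table, 0.874 and 0.866 with both channels above background, 0.825 and 0.815 with the median over probes, and 0.847 and 0.841 with offset 16. Pearson's r was 0.892 with median centring and 0.844 with the processed signals. The 3' feature of RSP3584 turned to -0.037 with median centring. Unlike loess, median centring leaves a trend of ratio with brightness in place, and this feature was bright (mean log2 intensity 17.2). The cause of such a trend was not tested. The 3 features of region 0680 stayed between 1.25 and 1.92 over the alternatives. Over 13 alternatives with a test on arrays, named features lost a call in 7 cases, RSP3584 included. Base content correction and gene list alternatives were not run, and no test was made on a single array, which leaves no residual degree of freedom. The lower share of Cy5 spots well above background limits ratios, at 76.9% in replicate 2 against 95.1% in Cy3. The median intensity there was not lower in Cy5 (4951 against 4551.75 in Cy3).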

Other observations

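The tests in this part (agreement of probes, brightness-matched features, the bright run under other processing, and correlation of neighbours) were chosen after the results were seen. In 1 run of 46 close identifiers (mean log2 ratio 0.18), 22 features were called higher and 3 lower (camera adjusted p = 0.00335; adjusted p = 0.456 with an estimated correlation). None of them was 1.5-fold on both arrays, and neither p-value settles whether the run as a whole differs.

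The first pattern is that limma called 49.0% of features, most with small ratios. If bias of single probes were the whole cause, probes of 1 feature would share nothing, but their intraclass correlation was 0.338 (95% bootstrap interval 0.311 to 0.368; 4307 features). Part of it may still come from single probes, since the deviation of a probe from its feature's mean repeated between arrays with a correlation of 0.705. A dye bias common to all probes of a feature, or a true difference between strains, stays open, as the dyes were not swapped.

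The other pattern is the lower signal of the 54-feature bright run, all of it among the 100 brightest features. Its median log2 ratio stayed negative under the alternatives, between -1.58 and -0.62, so its direction did not depend on which of them was used. Its size did. Loess was not refitted without the run, so these values cannot exclude normalization as a cause. Bias of the brightest spots may contribute and cannot be told apart from a change of these features, because a change in ratio itself moves the brightness used for matching. Set against other features within 0.5 of their log2 brightness, members differed by a median of -0.27 (95% bootstrap interval -0.40 to -0.14) when matched on both channels, by 0.04 (-0.08 to 0.12) on Cy5 and by -0.55 (-0.70 to -0.40) on Cy3. A difference between the strains stays open, untested, because strain and dye were confounded.

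Numeric identifiers next to each other had similar log2 ratios (r = 0.353 across 4246 pairs outside the bright run; highest of 100 shuffled orders 0.03). A hypothesis of co-transcription of neighbours as the only cause was tested at a distance of 10 identifiers, where r was still 0.105 (highest shuffled 0.04). Shared transcripts that span such a distance would give this as well, so the value does not decide the question. Regional base content may contribute and was not tested.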
